A study of Dicentrarchus labrax with 88 samples.

How the data were processed

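Methylation was measured by epiGBS in red blood cell DNA of 88 samples of European sea bass. Per the labels, DNA was digested with MspI and SbfI, each sample received its own combination of adapters, and the samples were then pooled into a single library, which was nick-translated and sequenced with paired ends. The submitters name Trim Galore, Bismark and methylKit; their versions, settings and the genome build are not given in the sources used here. The authors' files list, for each cytosine, a coverage that is a count of reads. The deposited freqC and freqT values are the percent of those reads that read as C (methylated) and as T (unmethylated). No listed cytosine had fewer than 20 reads, so neither the planned minimum of 10 reads nor its alternative of 20 removed anything, and an alternative of 40 was added after the data had been seen. Methylated reads were recovered as reads times percent; the product was within 0.1 of a whole number for at least 99.9% of the cytosines of each sample, and the largest deviation was 0.461. The labels name no molecular identifiers, and PCR reads without them are not independent molecules. Reads of a region are summed over its cytosines, so a read that spans several of them is counted several times. Intervals given for single samples (Wilson, 95%) treat these counts as independent. They are therefore too narrow as counting error and cover no other error. Total reads, also summed over the listed cytosines, ran from 2128991 to 45606719 per sample.

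Samples were grouped by their treatment label into 44 pre-stress and 43 post-stress samples. Sample D15 with contradicting labels was left out of every comparison of groups or families. It was among the samples from which the library classes, the order of deposition and the cytosines of the global level were read. The groups, tests, thresholds, alternatives and the rule for named cytosines were fixed before the data were examined. A cytosine was tested if at least 50% of the samples of each group listed it. The test was a quasi-binomial logistic regression on methylated and total reads with family as covariate, with the dispersion from Pearson residuals not below 1, an F test and Benjamini-Hochberg adjustment, two-sided. A cytosine was called at an adjusted p below 0.05 with group means at least 10 points apart in the direction of the coefficient. Regions joined at least 3 tested cytosines over gaps of at most 200 bp and were tested in the same way on summed reads. The global level was the mean over cytosines listed in at least 90% of the samples, with a missing value filled by that cytosine's mean. Its family-adjusted difference was tested with 100000 permutations of the labels within families. Families were compared on 1 sample per fish code among families with at least 3 such fish, with an F test of all family terms. Variance was split by a permutational analysis of variance with 100000 permutations. The interaction used families with at least 3 samples in each group.

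Named cytosines were the 12 called ones with the largest rise and the 12 with the largest fall, at most 1 per 10 kb, the 10 called regions with the smallest p, and the 10 called cytosines with the widest range of family means. Comparisons of genomic features and of gene lists had been planned but were not run, because no genome or annotation that shares the positions of the files was at hand.

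The library classes were found after the data had been seen. A switching cytosine was listed in at least 50% of the samples and was below 15% or above 85% in at least 90% of the samples listing it, with at least 6 samples in each state. Such cytosines were joined by average linkage up to a distance of 0.3 (1 minus correlation), and the 3 largest clusters gave the classes. The 2 largest clusters were taken as unlisted in a sample that lists under 25% of their cytosines, and the third was read only where the second was listed and at least 3 of its own cytosines were. A cytosine followed the class if at least 70% of its variance lay between classes with class means at least 10 points apart; at thresholds of 50%, 80% and 90% in place of 70%, 48, 45 and 42 of the called cytosines did so instead of 47. The order of deposition and the prefixes and codes in the deposited names were examined last. A fit with family and class as covariates, a fit on the runs of neighbouring samples that hold both groups, and a paired fit on 9 identity-checked pairs were added.

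Alternatives set beforehand covered the minimum of reads, the share of samples listing a cytosine, cytosines that look like genotypes, very deep cytosines, reads of both strands summed, no family covariate, the fish as block in a paired test, 1 sample per fish, other thresholds, limma on log2 ratios of methylated to unmethylated reads (each plus 1), the gap between cytosines of a region, other sets of cytosines for the global level, and families with at least 5 fish. The tests were tried on simulated data of the same depths with 20000 cytosines. Of 100 cytosines changed by 12 points the regression recovered 85, and of 100 changed by 20 points all 100, with 0 false calls. All changed cytosines were drawn from those with intermediate mean levels. Of cytosines that follow the class without a change by group, 79 of 100 were called with family alone and 0 with family and class. Their levels were set by the first letter of the class alone, so the 0 with that class kept follows from the simulation. It says nothing about differences that the class does not capture, such as runs within a class. With family and class kept, 23 of 50 cytosines changed by 12 points and 46 of 50 changed by 20 points were recovered. Among families 199 of 200 were recovered with 25 false calls, and for the interaction 165 of 200 with 21 false calls. Computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1.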

Results

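DNA methylation was measured in red blood cells of juvenile European sea bass (Dicentrarchus labrax), which keep their nucleus in fish. The blood came from fish of 20 reared families. A sample taken before any challenge, at 6 months of age, is called pre-stress here. A sample taken at 9 months, at the end of a series of crowding and net-chasing challenges, is called post-stress. The files held 44 pre-stress samples and 43 post-stress samples from 19 families, and 1 further sample, D15, whose title says post-stress while its treatment and age labels say pre-stress. That sample entered neither group. The design text of the series states 74 samples while 88 are held, and which of them the study used is not given in the sources used here. The method, epiGBS, sequences bisulfite-treated restriction fragments, so each value is the methylation level of a single cytosine of a CpG, in percent of its reads. In all, 146409 cytosines on 25 linkage group names were listed in at least 1 sample. Linkage group names and positions are those of the files, the genome build is not given in the sources used here, and no gene annotation was at hand.

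Depth was similar in both groups. Total reads over listed cytosines ran from 3488214 to 45606719 per pre-stress sample and from 2128991 to 30703215 per post-stress sample. The unassigned sample had 16622186 reads. The difference of log10 total reads, post-stress minus pre-stress, was -0.0265 (two-sided permutation test, p = 0.604). A sample listed 56344 to 111906 cytosines before stress and 49588 to 110707 after stress. The median number of reads per listed cytosine ran from 45 to 304 and from 37 to 221 in the same order. No listed cytosine had fewer than 20 reads. Samples of both groups exist for 15 families. Age and treatment changed together and no unstressed fish of 9 months was sampled, so every difference below is one between 2 occasions that differ in both.

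The samples also fell into sets that the labels do not name. At 139 cytosines the level was below 15% or above 85% in nearly every sample and switched between these states. The 3 largest groups of such cytosines that switched in step held 48, 31 and 14 cytosines on 18, 15 and 8 linkage group names. Their states sorted the samples into 8 classes, called library classes here. Each class name gives the state of the 3 groups in turn, with H for near 100%, L for near 0 and n for a group that was mostly unlisted. Class LHH held 25 pre-stress and 3 post-stress samples, class LLL 14 and 2, class HHH 2 and 5, and class Lnn 3 and 4. The other 29 post-stress samples lay in classes without a pre-stress sample, among them 14 in class Hnn, 7 in class LHL and 7 in class nHH. Class nnn held only post-stress H2, the sample with the fewest reads. It listed 20.8%, 3.23% and 21.4% of the cytosines of the 3 groups, with median levels of 98.3%, 92.6% and 100%. Its separate class and run may thus reflect low coverage. In the order of deposition the class changed only 12 times between 87 pairs of neighbours, so that the samples formed 13 runs, of which 8 were 7 samples long. In random orders within the groups it changed at least 47 times (permutation test, p = 1e-05, the smallest that 100000 permutations can give). Only 2 runs held both groups, 1 with 18 pre-stress and 3 post-stress samples of class LHH and 1 with 3 and 4 samples of class Lnn. The heat map of switching cytosines shows the classes.

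**Figure D1:**
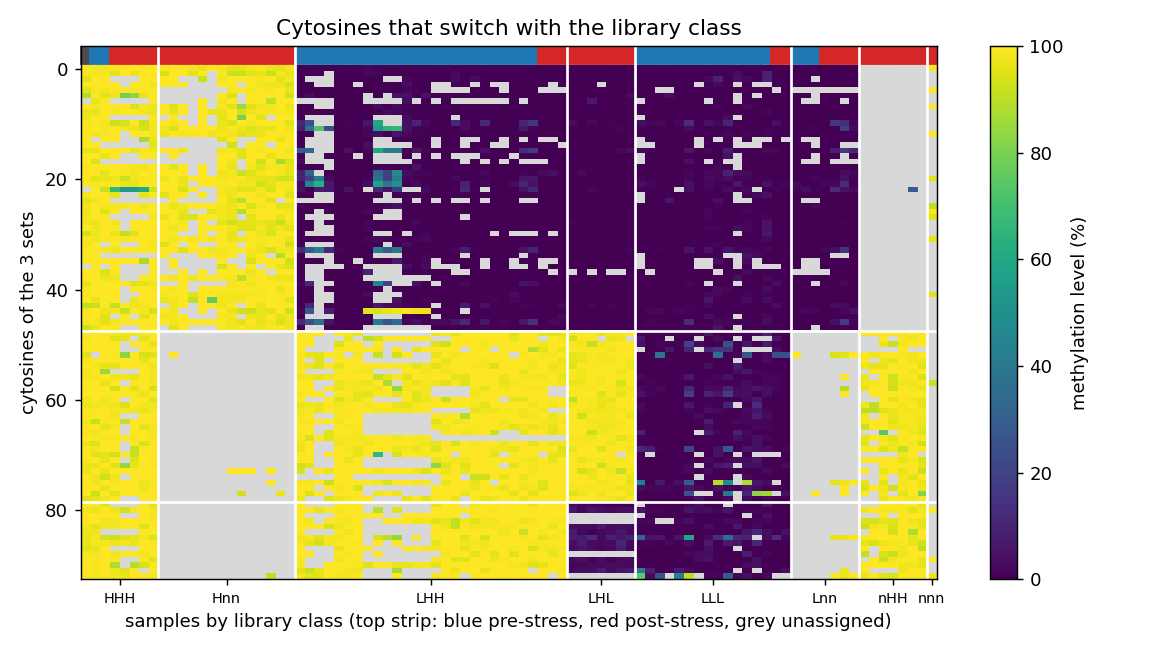
Methylation level (colour, percent) of the cytosines of the 3 largest groups that switch in step (48, 31 and 14 lines from top to bottom, parted by white lines) in 88 samples sorted by library class. The strip at the top marks pre-stress samples in blue, post-stress samples in red and the unassigned sample in grey, and light grey cells are unlisted; class LHH is mostly blue (25 of 28 samples), while classes Hnn, LHL and nHH hold red samples only.

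The comparison of post-stress with pre-stress samples at single cytosines asked where methylation differed after the challenges. The clearest differences lay in 3 short stretches. Next to position 18663154 on LG1A methylation fell, at this cytosine from 49.2% ± 10.2 (SD, n = 44) to 28.0% ± 9.37 (SD, n = 43), with a median of 155 reads per sample. On LG6, over 8 cytosines around position 21672643, it fell as well, from 25.0% ± 7.85 (SD, n = 44) to 11.8% ± 3.81 (SD, n = 43) at a median of 1063 reads summed over the 8. At position 23055559 of the sequence named UN it rose, from 53.5% ± 6.40 (SD, n = 44) to 65.3% ± 4.94 (SD, n = 43) at a median of 452 reads. The largest changes by size, however, were switches between unmethylated and fully methylated states, such as position 5015700 on LG10, with 4.56% ± 20.7 (SD, n = 44) before and 54.6% ± 49.5 (SD, n = 36) after stress at a median of 167 reads, and these followed the library class.

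Of 87668 cytosines tested by quasi-binomial regression with family as covariate, 1567 had an adjusted p below 0.05, 1267 of them higher and 300 lower after stress. Of these, 115 also differed by at least 10 points and were called, 59 higher and 56 lower after stress. Among the called cytosines 47 followed the library class, which here means that at least 70% of their variance lay between classes with a range of class means of at least 10 points. They made up 37 of the 59 rises and 10 of the 56 falls. The other 68 comprised 22 rises and 46 falls. With family and library class both kept in the model 17 cytosines were called, 2 higher and 15 lower, and all 17 were among the 115. They lay in 4 stretches: 8 on LG6, 6 on LG1A, 2 on UN and 1 on LG8. Cytosines on both strands of a CpG are tested and counted separately. On LG6 and LG1A both strands of each CpG concerned were called. On UN the other strand, at 23055560 and 23055618, changed by 11.4 and 9.49 points, with adjusted p of 0.274 and 0.0760 in this regression. On LG8 the other strand, at 13049290, changed by -7.39 points with an adjusted p of 0.758.

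All 12 cytosines with the largest rises followed the library class. They lay at LG4 4861963, LG10 5015700, UN 49464406, LG12 19815259, UN 15016839, LG10 12818741, LGx 16056882, LG20 3749622, LG22-25 1711302, LG8 827064, LG16 16325746 and UN 30938671, and rose by 50.2 points at most and 44.2 points at least. With the class kept their adjusted p lay between 0.736 and 1.0. Of the 12 largest falls 8 followed the class. These were LG1A 9341832, LG2 18920686, LG14 11422484, LG15 2436448, LG8 7840153, LG16 1640233, UN 43657011 and LG15 17849071, with changes of -24.5 to -13.9 points. The remaining 4 were LG24 863186, LG1A 18663154, LG6 21672643 and LG9 16135560.

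Among called cytosines that did not follow the class, chosen by the same rule after the classes had been seen, the largest rises were LG14 1417136, LG15 19323386, LG24 1971304, LG9 20261227, LG4 20447252, LG22-25 9946405, LG9 18550332, LG15 14847436, UN 23055559, LG19 17792662, LG10 11845126 and UN 25227041. The level at LG19 17792662 rose from 27.8% ± 9.88 (SD, n = 44) to 39.6% ± 12.0 (SD, n = 43) at a median of 276 reads, with an adjusted p of 5.88e-04. At LG14 1417136 it rose from 45.6% ± 45.9 (SD, n = 23) to 71.3% ± 32.2 (SD, n = 22) at a median of 52 reads. The largest falls were LG24 863186, LG1A 18663154, LG6 21672643, LG9 16135560, LG1B 11512372, LG7 5257163, LG1A 5703936, UN 19801932, LG4 24346231, LG5 5825989, LG12 20709583 and LG2 19710132. At LG7 5257163 the level fell from 60.1% ± 12.2 (SD, n = 44) to 46.8% ± 16.2 (SD, n = 41) at a median of 61 reads, with an adjusted p of 9.41e-04. At LG24 863186 it fell from 50.7% ± 38.6 (SD, n = 32) to 27.8% ± 38.8 (SD, n = 29) at a median of 62 reads. The SDs at LG14 1417136 and LG24 863186 show samples spread over much of the range. No genotypes were at hand, so a DNA variant is not excluded at them. Of these 24 cytosines only UN 23055559, LG1A 18663154 and LG6 21672643 stayed past the threshold with the class kept, with adjusted p of 5.09e-03, 3.19e-05 and 2.35e-08.

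The 17 cytosines called with the class kept were then followed through the regions that hold them, a choice made after seeing them. In the test with family alone the regions on UN, LG6 and LG1A had rank 1, 2 and 3 by p among all 7840 regions, and the region on LG8 had rank 1209. On LG6, between 21672627 and 21672716, 8 cytosines gave a level of 25.0% ± 7.85 (SD, n = 44) before and 11.8% ± 3.81 (SD, n = 43) after stress, a change of -13.3 points. All 43 post-stress samples lay below the pre-stress median of 25.6%, and the level was lower after stress in 15 of 15 families and in 8 of 8 fish codes found on both occasions, among them R15, whose samples did not match as the same fish. On UN, between 23055525 and 23055657, 10 cytosines gave 66.3% ± 3.79 (SD, n = 44) before and 74.9% ± 2.84 (SD, n = 43) after stress, a rise of 8.60 points seen in 43 of 43 post-stress samples against the pre-stress median of 66.0%, in 15 of 15 families and in 8 of 8 fish codes. On LG1A, between 18662868 and 18663309, 22 cytosines together changed from 24.4% ± 5.02 (SD, n = 44) to 18.1% ± 3.48 (SD, n = 43), or by -6.29 points, while the 6 called cytosines in it changed by -21.2 to -11.8 points. The LG1A level was lower in 8 of 8 fish codes, with changes of only -0.729 points in I16 and -0.248 points in T16. It was also lower in 41 of 43 post-stress samples against the pre-stress median of 24.1%, and in 14 of 15 families. The exception was family J, with 1 pre-stress and 2 post-stress samples, where the difference was 7.10 points. Its pre-stress sample J9 was at 9.61% with 957 reads, against a median of 3303 reads. The cytosines of the LG1A region had pre-stress means from 0.696% to 77.4%. The summed level of a sample thus also depends on how its reads are spread over them, which does not touch the single called cytosines. The region on LG8, between 13049289 and 13049609, changed by -0.809 points as a whole, with 1 called cytosine that changed by -10.9 points.

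With family as covariate the adjusted p of the LG6, UN and LG1A regions was 6.66e-15, 2.10e-15 and 2.96e-14. With family and library class it was 9.46e-08, 1.67e-05 and 1.67e-05, against 0.179 for the LG8 region. Median reads per sample, summed over the cytosines of each region, were 1063 on LG6, 3401 on UN and 3303 on LG1A. In the classes HHH, LHH, LLL and Lnn the difference, post-stress minus pre-stress, was -23.5, -13.4, -10.2 and -17.0 points on LG6. It was 8.99, 9.99, 8.10 and 9.24 points on UN, and -15.8, -6.18, -7.28 and -5.46 points on LG1A. In the LG8 region it was -6.66, -0.315, -1.99 and 0.0515 points. Within the 2 runs of neighbouring samples that hold both groups the difference was -14.6 points on LG6, 10.1 points on UN and -4.93 points on LG1A. Exact permutation tests within runs gave p = 4.3e-05, 4.3e-05 and 0.0288, with family not kept. The samples of these runs also took part in the choice of the regions, so these p-values are not a separate test of them. In the run of class Lnn only family S had samples of both groups. The plot of levels per sample and the map of single cytosines show these 3 regions.

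**Figure D2:**
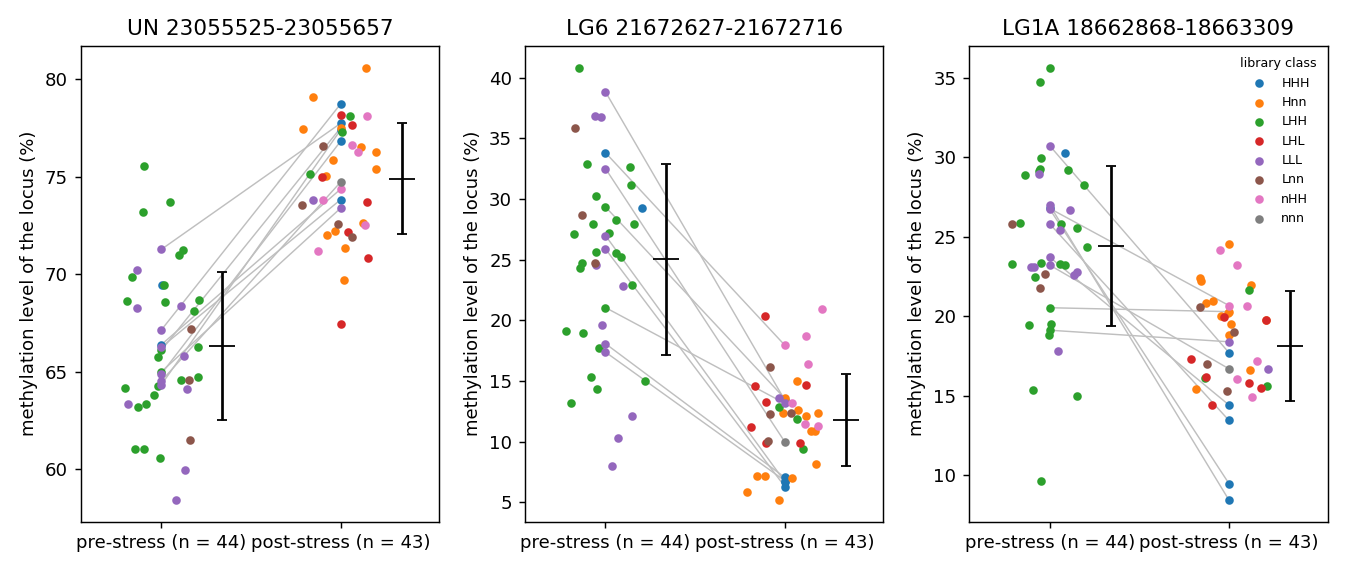
Methylation level in percent of the regions on UN, LG6 and LG1A in 44 pre-stress and 43 post-stress samples, 1 point per sample coloured by library class; black bars give mean and SD and grey lines join the 9 pairs of samples assigned to the same fish. After stress the mean was 74.9% against 66.3% on UN, 11.8% against 25.0% on LG6 and 18.1% against 24.4% on LG1A.

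**Figure D3:**
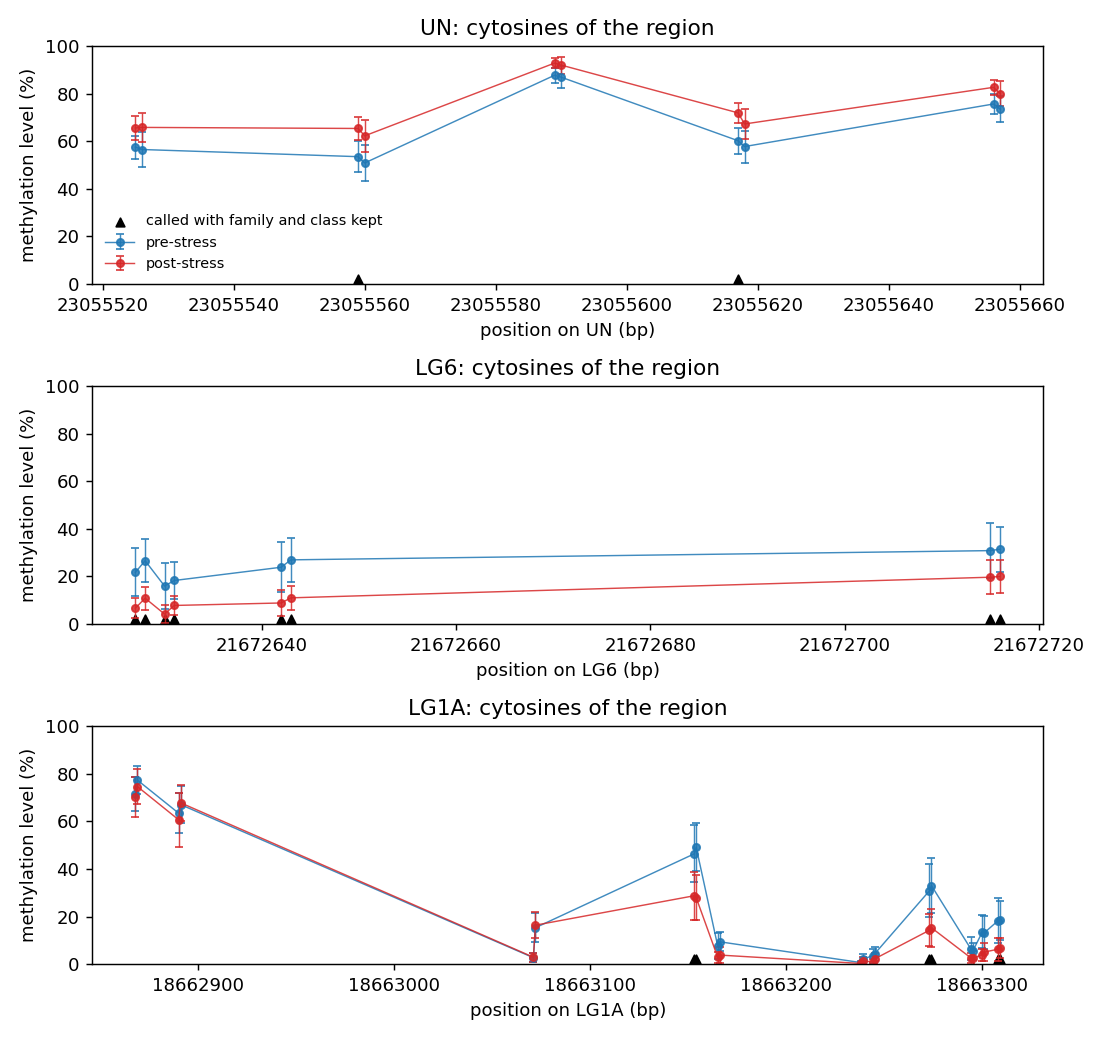
Mean methylation level (percent, bars are SD) at each tested cytosine of the 3 regions against its position in bp, pre-stress in blue and post-stress in red. Triangles mark cytosines called with family and library class kept, 2 on UN, 8 on LG6 and 6 on LG1A; on LG1A they lie at the right end of the region.

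The comparison of regions, made of at least 3 tested cytosines with gaps of at most 200 bp, asked whether neighbouring cytosines differed together. Methylation fell in 2 called regions, the one on LG6 described above and LG7 5256995 to 5257227, which changed from 47.8% ± 12.1 (SD, n = 44) to 37.7% ± 12.1 (SD, n = 41) at a median of 367 reads. It rose in 13 called regions, of which LG10 11845115 to 11845167 and LG9 20261226 to 20261372 held no cytosine that follows the library class. The former rose from 32.7% ± 10.6 (SD, n = 44) to 43.0% ± 12.9 (SD, n = 43) at a median of 894 reads. The latter rose from 43.5% ± 19.1 (SD, n = 44) to 55.2% ± 14.4 (SD, n = 43) at a median of 2875 reads. The other 11 rises each held 1 or 2 cytosines that follow the class.

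In all 7840 regions were tested, with a median of 8 cytosines and 115 bp. An adjusted p below 0.05 was reached by 1742 regions, 1657 of them higher and 85 lower after stress, and 15 also differed by 10 points. The 10 called regions with the smallest p were LG6 21672627 to 21672716, LG20 16298563 to 16298630, LG7 5256995 to 5257227, UN 30938670 to 30938704, LG11 22079697 to 22079701, LG17 10021201 to 10021307, LG14 5582848 to 5582964, LG10 12818740 to 12818744, LG10 11845115 to 11845167 and LG14 28375395 to 28375480. The adjusted p was 8.20e-05 for the LG20 region, which rose by 10.5 points pooled and differed by 0.600, 3.98, 0.898 and -0.876 points within classes HHH, LHH, LLL and Lnn. It was 1.50e-04 for the LG7 region, which differed by -15.9, -12.5, -29.3 and -7.25 points within the same classes and was lower after stress in 6 of 7 fish codes. The exception was R15, whose samples did not match as the same fish, and all 8 pairs of samples matched as the same fish by correlation that have values were lower, each with its libraries in different classes. The LG10 region that begins at 11845115 differed by -4.88, 10.9, 3.29 and 18.3 points within them. With the class kept only the LG6 region was called, and 14 regions had an adjusted p below 0.05; the adjusted p of the LG7 region was then 0.215.

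The global level, the mean of 60682 cytosines listed in at least 90% of the samples, was compared to ask whether methylation shifted as a whole. It was 76.9% ± 0.577 (SD, n = 44) before and 77.7% ± 0.508 (SD, n = 43) after stress. The family-adjusted rise was 0.717 points, larger than the SD of either group (two-sided permutation test within families, p = 1e-05, the smallest that 100000 permutations can give). It was higher after stress in all 15 families with both groups, by 0.104 to 2.13 points. The rise came from cytosines with intermediate and high levels. It was 1.08 points at the 8850 cytosines with a mean between 20% and 80%, 0.983 points at the 31539 cytosines between 80% and 95% and 0.257 points at the 13249 cytosines above 95%, with an adjusted permutation p of 1.67e-05 for each. At the 3624 cytosines below 5% the difference was -0.0126 points (permutation p = 0.748), and at the 3420 cytosines between 5% and 20% it was -0.113 points (permutation p = 0.560). The plot of levels by family shows the shift.

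Within the classes HHH, LHH, LLL and Lnn the global difference was -0.155, 1.04, 0.0687 and 0.148 points, and with family and class kept it was 0.361 points (permutation test within classes, p = 0.0902), which is not past the threshold. Within the 2 runs that hold both groups it was 0.683 points (exact permutation test, p = 0.0106, family not kept), made up of 1.04 points in the run of class LHH and 0.148 points in the run of class Lnn. Samples also carry 3 prefixes, C, HR and LR, that the labels do not explain, and within them it was 0.234, 0.803 and 0.938 points. In the same order the difference was -17.9, -13.0 and -11.8 points on LG6, 9.86, 9.06 and 7.73 points on UN, -12.4, -3.97 and -6.42 points on LG1A and -5.59, 0.131 and -0.0577 points in the LG8 region; whether the prefixes differ was not tested, and what they stand for is not given in the sources used here. In the paired comparison of the 8 fish codes, with the code as block, it was 0.483 points, higher in 7 of 8 codes (exact sign-flip test, p = 0.0312). These include R15, at 0.441 points, whose samples did not match as the same fish. For the 9 pairs whose identity the data bore out it was 0.386 points, higher in 7 of 9 pairs (exact sign-flip test, p = 0.0547).

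**Figure D4:**
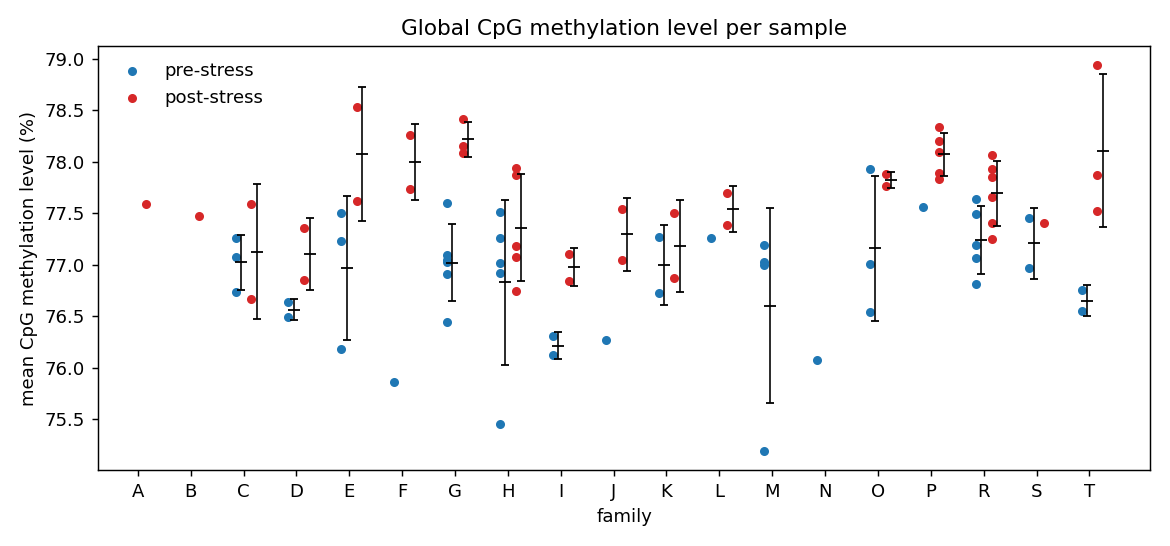
Mean CpG methylation level (percent) of each sample by family, pre-stress in blue and post-stress in red, with black bars for mean and SD where a family has more than 1 sample. The post-stress mean was above the pre-stress mean in all 15 families that have both groups.

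Families were compared because every sample is labelled with its family. Levels differed between families at many more cytosines than between the occasions. A range over many small families is, however, wider by construction than a difference between the group means. At 6209 of 89376 tested cytosines (6.95%) the family means differed, with a median range of 38.8 points between the lowest and the highest family. The range was at least 25 points at 4450 of them, at least 50 points at 2176 and at least 75 points at 836. At LG14 24500788 the level was 0% ± 0 (SD, n = 3) in family P and 100% ± 0 (SD, n = 2) in family G, with a median of 60.5 reads per sample. The other cytosines of the 10 with the widest range, all 100 points wide, were LG10 746402, LG11 113316, LG11 22079697, LG11 23938343, LG12 19440770, LG13 18584532, LG14 1866492, LG14 23176498 and LG17 102323. Of these LG11 22079697 follows the library class, and LG11 22079697, LG11 23938343, LG13 18584532 and LG17 102323 have levels near 0, 50 or 100% in nearly all samples, the pattern a DNA variant gives. Most of these widest ranges rest on families with 1 to 3 samples at an end. No genotypes were at hand, so a DNA variant is not excluded at LG14 24500788 or at other cytosines without this pattern.

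The family test used 76 samples of 16 families with at least 3 fish, 1 sample per fish code, and kept the group in the model. By the identity check below, H55 with H5 and D11 with D1 were each the same fish but entered as separate ones. Pre-stress R15 entered as family R but was closest to family P. Without pre-stress R15 and post-stress H5 and D1 the test called 6063 cytosines. Neither this test nor the analysis of variance below kept library class, run or prefix. Families F, G, M and S carried only prefix LR, and E, I, J, L, N and O only HR. Family and prefix are thus partly confounded. Of the 6209 cytosines 580 had the pattern a DNA variant gives, and 26 followed the library class. Only 712 tested cytosines had this pattern, so most of those with it were called. Over all listed cytosines 302 of the 1398 with the pattern followed the library class, so the pattern alone does not show a variant. Of the 115 cytosines called between the occasions 51 were also called between families, as were 32 of the 68 that do not follow the class. In a permutational analysis of variance over the 60682 cytosines family took 39.5% of the variance, against 20.0% expected for that many families with no effect, and the stress group took 1.77%, against 1.33% expected (permutation tests, p = 1e-05 each, the smallest that 100000 permutations can give). The median correlation of deviations from the group means was 0.248 between samples of the same family and -0.0383 between samples of different families.

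Whether the change with stress itself differed between families was tested in the 3 families with at least 3 samples in each group. Family G had 6 pre-stress and 3 post-stress samples, family H had 5 and 5, and family R had 5 and 6. The pre-stress samples of family R include R15, which was closest to family P. Without it the regression below called 0 cytosines as well, while the tests of the regions and the global level were not repeated. On LG6 the change was -3.97 points in family G, -18.9 in family H and -19.3 in family R, a difference that did not pass its test (permutation p = 0.0579). On UN the families changed by 7.95, 6.78 and 7.19 points (permutation p = 0.920), on LG1A by -4.27, -7.27 and -10.3 points (permutation p = 0.165), and in the global level by 1.20, 0.531 and 0.454 points (permutation p = 0.218). No cytosine of 90187 was called for an interaction by the quasi-binomial regression on these 30 samples, while 5420 (6.01%) had an unadjusted p below 0.05. On simulated data of this size the test found 165 of 200 cytosines of intermediate level whose change differed by 30 points between families, and no smaller difference was simulated.

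The identity of fish sampled on both occasions was checked from the correlation of deviations from the group means at the cytosines of the global level. For 7 of the 8 fish codes found in both groups the 2 samples were each other's best match, with correlations of 0.423 to 0.667. The samples called R15 correlated at -0.0178. The pre-stress sample R15 was closest to family P (median correlation 0.312, against -0.00151 with family R). Pre-stress H55 and post-stress H5 were each other's best match at 0.533, as were pre-stress D11 and post-stress D1 at 0.646, and for 2 of these samples the code given with the deposited data was that of the partner. Together with the 7 codes they make the 9 identity-checked pairs. In these pairs the change was -16.5 ± 5.90 points on LG6, 9.85 ± 2.31 points on UN and -9.35 ± 6.58 points on LG1A (SD, n = 9). Exact sign-flip tests gave p = 0.00391 for each, the smallest that 9 pairs allow. These samples also took part in the choice of the regions. The pairs C1, C12, H2, R18, H55 with H5 and D11 with D1 all carry prefix C. Their pre-stress samples lie in a single run, and their post-stress samples except H2 lie in a single other run. With regard to a difference between runs or prefixes the pairs are thus not independent. The largest LG1A falls, -18.6 points in C1 and -17.3 points in H55 with H5, involve post-stress samples with 498 and 1267 reads there. In the pairs of prefix HR, I16 and T16, LG1A changed by only -0.729 and -0.248 points.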

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

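The tests for samples that lie apart were set beforehand, while the regions they were applied to, the library classes and all tests of explanations given here were chosen after the results had been seen.

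For each of 4 measures 7 sets of samples of the same family and group were tested, 28 tests in all, and 3 samples lay apart from the others of their set; chance marks about 1 in 20 such tests. The global level of pre-stress sample H9 was 75.5%, against 76.9% to 77.5% in the 4 others of its family. That of pre-stress sample M18 was 75.2%, against at most 77.2% in the 3 others. The LG1A region of post-stress sample H5 was at 9.47% (95% Wilson interval 7.98% to 11.2%, 1267 reads), against 15.3% to 16.7% in the 4 others. The median over samples was 3303 reads. The LG1A region sums reads over cytosines of unlike levels, so another spread of reads over them is not excluded for H5. A read that spans several cytosines is counted several times, so the intervals given for regions are too narrow. Without these 2 pre-stress samples, pre-stress R15 and post-stress H2 the global rise was 0.681 points. Among the UN, LG6 and LG1A regions, the unassigned sample D15 lay outside the pre-stress range at 2. It also did so at the called LG20 region, which holds class followers, with 93.5% against 64.3% to 91.8%. Its UN region was at 78.0% (95% Wilson interval 76.8% to 79.1%), against 58.4% to 75.6% in pre-stress samples, and its LG6 region was at 6.32% (5.19% to 7.68%), against 7.98% to 40.8%.

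Of the 115 called cytosines 36 switch between states near 0 and near 100%. Most of them define the library classes and cannot test them, but the 6 outside the defining sets differed by a median of 0.494 points within classes, against 16.3 points pooled, which is consistent with a difference between library classes. A DNA variant is argued against, since 65.7% of 204 comparisons of a fish with itself moved by over 70 points. The class changed only 12 times between 87 neighbours in the order of deposition, so an adapter or a place in the library preparation shared by neighbours is a candidate source, which the labels do not allow to be read.

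The global level rose by 0.717 points with family kept. Depth is argued against, since the rise was 0.732 points with log10 total reads kept, and so is poorer conversion, since cytosines below 5% changed by -0.0126 points. A difference between library classes and a rise with stress cannot be told apart, since with the class kept the rise was 0.361 points (permutation p = 0.0902) and 29 post-stress samples lie in classes without a pre-stress sample. Within runs of neighbouring samples it was 0.683 points (exact permutation p = 0.0106), but this rests on 1 of 2 runs with 3 post-stress samples. Age, 6 against 9 months, stays open as untested.

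The regions on LG6 and LG1A fell and the region on UN rose. They ranked 1 to 3 of 7840 by p with family alone, and a difference between library classes as their whole cause is argued against, since 12 of 12 comparisons within classes had the pooled sign and the largest adjusted p with the class kept was 1.67e-05; the LG8 region, found with the class kept, had an adjusted p of 0.179. A DNA variant or another make-up of families is argued against as well, since 27 of 27 comparisons of a fish with itself, in 9 pairs, went the way of the groups. On LG1A, however, the change was only -0.729 points in I16 and -0.248 points in T16, so there the argument rests on the other pairs. None of the 9 pairs has both libraries in the same class, and most of them carry prefix C with their pre-stress samples in a single run. On LG1A the exact permutation p within the runs of neighbours, family not kept, was 0.176 and 0.0571. In classes HHH and LLL the pre-stress and post-stress samples came from different runs, so those comparisons cannot tell the groups from the runs. As a hypothesis these regions may have changed in the fish between the occasions, with stress and age both open, since no unstressed fish of 9 months was sampled.

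Chance was tested with other splits of the samples that kept the group sizes and parted the 8 shared fish codes, but did not hold the library class. Of 100 splits only the real one called as many as 115 cytosines, and the highest of the others called 9. The same held once cytosines that follow the class were left out, with 1 of 100 splits and a highest other of 9. For regions it was 1 of 100 splits, with 15 called against a highest other of 2. With family and library class kept and labels shuffled within classes it was 1 of 100 splits, with 17 cytosines called against a highest other of 7. Random regrouping of the samples thus did not account for the counts of 115, 15 and 17. None of these splits held the runs, and the shuffle within classes mixed runs of the same class. A difference between runs is therefore not excluded for any of these counts. Library class is also not excluded for the called cytosines and regions outside the 17 cytosines and 1 region called with the class kept. Outside them the LG7 region was lower within all 4 classes that hold both groups and in 8 of 8 identity-checked pairs. Its adjusted p was 0.215 with the class kept. The LG9 region that begins at 20261226 was higher in all these classes and in 9 of 9 such pairs, with an adjusted p of 0.754. The LG10 region that begins at 11845115 was higher in 6 of 9 such pairs. In the runs of neighbours that hold both groups 0 cytosines were called by the quasi-binomial regression, with 5560 at an unadjusted p below 0.05. For families it was 1 of 40 reassignments, with 6209 called against a highest other of 136. For the interaction, with 0 called and 5420 at an unadjusted p below 0.05, the test says nothing, since any reassignment gives at least 0; 40 of 40 did, the highest being 28.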

How the results depend on the processing

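In all 48 alternatives set beforehand and 32 chosen after seeing the data were run, among the latter every one that names the library class, the runs or the identity-checked pairs. The global rise kept its sign in every alternative run for it. The balance of called cytosines did not: 59 were higher and 56 lower, against 26 and 45 at 80% listing, 30 and 48 without genotype-like cytosines, 35 and 42 without shared fish codes, 21 and 46 without class followers and 2 and 15 with the class kept. It went the other way with 1265 and 299 by adjusted p alone, 94 and 60 without the family covariate, 66 and 40 by limma, 21 and 0 at stricter thresholds, 6 and 2 with the fish code as block and 19 and 5 with the identity-checked pairs. Called regions went from 13 higher and 2 lower to 0 and 1 with the class kept. The share of variance by family and by group and the interaction kept their side of the threshold in every alternative run for them. A minimum of 20 reads changes nothing by construction, since every listed cytosine has at least 20 reads. The comparisons of genomic features and gene lists were not run, since no annotation was at hand. Fits with the class kept have less power: on simulated data they found 23 of 50 cytosines of intermediate level changed by 12 points and 46 of 50 changed by 20 points.

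Against 115 called cytosines, 71 were called when 80% of each group had to list them, 8 with the fish code as block, 1564 by adjusted p alone with a difference of means in the direction of the coefficient, and 21 at an adjusted p below 0.01 and 25 points. Without class followers 67 were called, with family and class as covariates 17, and with the identity-checked pairs as block 24. In the runs of neighbours that hold both groups, 21 against 7 samples, the quasi-binomial regression called 0 cytosines, with 5560 of 84489 at an unadjusted p below 0.05. Against 15 called regions, 6 were called at 80% listing, 5 without genotype-like cytosines, 1742 by adjusted p alone, 5 without class followers, 1 with class as covariate and 1 with the identity-checked pairs as block. The same regression called 0 regions with the fish code as block (746 at an unadjusted p below 0.05), 0 at the stricter thresholds (2747) and 0 in the runs (796). The global rise of 0.717 points was 0.361 points with the class kept (permutation p = 0.0902) and 0.386 points in the 9 identity-checked pairs (exact p = 0.0547). Against 6209 cytosines called between families, 3993 were called with strands summed, where fewer positions are tested, and 3523 among families with at least 5 fish. Adjusted p alone and stricter thresholds change counts by construction; for the others the cause was not tested.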

Other observations

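The regions and cytosines compared here were chosen after the results had been seen.

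The unassigned sample D15 correlated with pre-stress D15 at 0.754, each being the other's best match. Its global level was 77.3%, against 76.5% in pre-stress D15. Its UN region was at 78.0%, against 68.4% (95% Wilson interval 67.5% to 69.3%) in pre-stress D15. Its LG6 region was at 6.32%, against 24.6% (23.4% to 25.9%), and its LG1A region was at 15.7% (14.7% to 16.8%), against 23.1% (22.3% to 23.9%). The differences have the signs of the post-stress group in these 4 measures, but not in every called region. The LG7 region that begins at 5256995, lower after stress, was at 64.3% in unassigned D15 (95% Wilson interval 59.5% to 68.7%) and 61.9% in pre-stress D15 (59.4% to 64.3%). The LG9 region that begins at 20261226, higher after stress, was at 19.5% in unassigned D15 (17.997% to 21.1%) and in pre-stress D15 (18.6% to 20.5%), below the lowest post-stress sample at 28.3%. The number in its deposited name lies within the range of post-stress samples and above that of every pre-stress sample. It belongs to class HHH, and its own run in the order of deposition holds 5 post-stress samples and no pre-stress sample. The other run of that class holds 2 pre-stress samples. The sample entered no comparison of groups or families.

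Of 109 cytosines that follow the library class 42.2% were outermost within 400 bp, against 28.05% of 2000 random tested cytosines; the difference was not tested.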
